A study of Caenorhabditis elegans with 2 samples.

How the data were processed

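Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans embryos of mixed stage and mixed sex, collected by egg bleaching with a labelled age of 3 hours. The worms were of strain OP349, which carries a transgene for CND-1 with a GFP-FLAG tag at its C-terminus, and the antibody was directed against GFP. CND-1 is a basic helix-loop-helix (bHLH) transcription factor of the NeuroD family. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and there were 2 biological replicates. Both replicates belong to 1 group, so the design holds no comparison between conditions, and the labelled control experiment was not used here.

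The authors made 4 peak lists. One list per replicate and 1 list for the pooled reads hold 30000 regions each, which per their labels contain peaks together with background as input for the irreproducible discovery rate (IDR) procedure. The fourth list is the thresholded one and holds 1964 peaks, all of them present in the pooled list with identical positions and signal. The signal column is the peak caller's own value as deposited by the authors, a non-negative measure of enrichment with no stated scale, and it was used to rank and split peaks within a list and to correlate the replicates across peaks. The authors' −log10 q-value took its maximum of 3.46 in 1459 of the 1964 thresholded peaks and was not used to rank them. The peak caller, the aligner and the IDR limit are not given in the sources used here. Coordinates are those of the ce11 assembly named in the labels, and every region ended within the chromosome lengths of the WBcel235 reference sequence, which is the same assembly. Sequencing depth is unknown from peak lists, so the intervals given cover the counting of peaks only.

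Gene positions came from Ensembl release 115, with 19973 nuclear protein-coding genes and 29314 distinct transcript starts. Each summit was placed in 1 category in the order promoter (500 bp upstream to 100 bp downstream of a transcript start of a protein-coding gene), 5′ UTR, coding exon, 3′ UTR, intron, other gene and intergenic. A protein-coding gene was called bound when a summit lay from 1500 bp upstream to 500 bp downstream of any of its transcript starts. Peaks on the mitochondrial genome were left out of these steps, which left 1940 nuclear peaks. Locations and numbers of bound genes were compared with 10000 random circular shifts of the summits along each chromosome, and the smallest two-sided permutation p this allows is 0.0002. Shares carry 95% exact Clopper-Pearson intervals, and the correlation an interval from 1000 bootstrap resamples of peaks.

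For 24 gene lists, Fisher's exact test compared the share of bound members with that of all other protein-coding genes, two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Of the listed members, 2 matched no annotated gene symbol. Genes with more annotated transcript starts have more windows in which a summit counts. Neither Fisher's test nor matching lists on upstream distance corrects for this or for differences in peak density between chromosomes. E-boxes, the CANNTG sites recognised by bHLH proteins, and all 2080 strand-collapsed 6-mers were counted as present or absent in the 100 bp centred on each summit and in a 100 bp window centred 300 bp to its left, and compared by the exact McNemar test. A 6-mer counted as enriched at an adjusted p under 0.05 and a share at least 1.5 times that of the flank. The share of peaks on X was set against its share of nuclear length by an exact binomial test. The strongest and weakest 485 nuclear peaks by signal were compared by Fisher's exact test. Peaks and genes that lie close together are not independent, which makes the p-values of Fisher's, McNemar's and the binomial test too small to an unknown extent.

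Each replicate's value was taken from its 1964 strongest regions, and its nuclear ones among these, and is given as the mean ± SD of the 2 replicates. A thresholded peak counted as shared when a summit among those regions lay within 100 bp of its own summit in both replicates. Because these replicate lists were the input from which the thresholded list was chosen, agreement between them was built into that list.

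Gene lists, tests, windows and the rule for naming genes were set before the data were examined. The rule named cnd-1 and hlh-2, the genes nearest to the strongest peaks until 20 genes were reached, up to 4 bound members per list with the strongest peak, up to 3 unbound members for lists with 6 or fewer bound members, all bound bHLH and homeobox genes, all 10 E-boxes, and the 10 enriched 6-mers with the largest ratio. Alternatives set at the same time were a stricter peak list, each replicate alone, merged peaks, other overlap rules, other promoter and gene windows, nearest genes, gene lists matched on upstream distance, and other sequence windows and flanks. Removing peaks within 100 bp of a tRNA, snoRNA or snRNA gene was chosen after seeing the data.

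The tests were tried on simulated data. With 30% of 2000 simulated summits planted in promoters, 50 of 50 sets passed, against 1 of 50 sets with none planted. With 5 of 10 gene lists raised to 4 times the background in 100 sets, 489 of 500 raised lists were found, and lists that were not raised passed 16 times. These 10 were the lists with 41 or more members, and binding was drawn for each gene independently. Shorter lists, such as the Wnt pathway and cell cycle regulators, were not simulated, so how often a raised short list would be found is unknown. A 6-mer planted in 200 of 2000 windows gave 210 more windows at summits than in flanks, and 5 other 6-mers of the 2080 also passed. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.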

Results

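Binding of GFP-tagged CND-1 was mapped by ChIP-seq in 2 biological replicates of mixed-stage C. elegans embryos. CND-1 is a bHLH protein of the NeuroD family. The thresholded list made from both replicates held 1964 peaks, of which 1940 lay on the nuclear chromosomes and 24 on the mitochondrial genome. The median peak was 396 bp wide, and overlapping peaks joined into 1925 regions. Signal, the authors' own value for each peak, ran from 103.07 to 1351.1 among nuclear peaks. All values below concern nuclear peaks.

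The same sites were found in both replicates for most peaks. Of the 1940 nuclear peaks, 1306 (67.3%, 95% exact interval 65.2 to 69.4) had a summit within 100 bp among the 1964 strongest regions of each replicate. After random shifts of the peaks this share averaged 0.273%. Replicate 1 alone held 80.98% of the peaks and replicate 2 held 83.4%. Across the 1854 peaks with a summit in both full replicate lists, the signals had a Spearman correlation of 0.707 (bootstrap interval 0.679 to 0.734) and a Pearson correlation of log2 signals of 0.791. These correlations run across peaks, which are not independent replicates, and the thresholded peaks had been chosen for ranking alike in the 2 replicates.

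**Figure D1:**
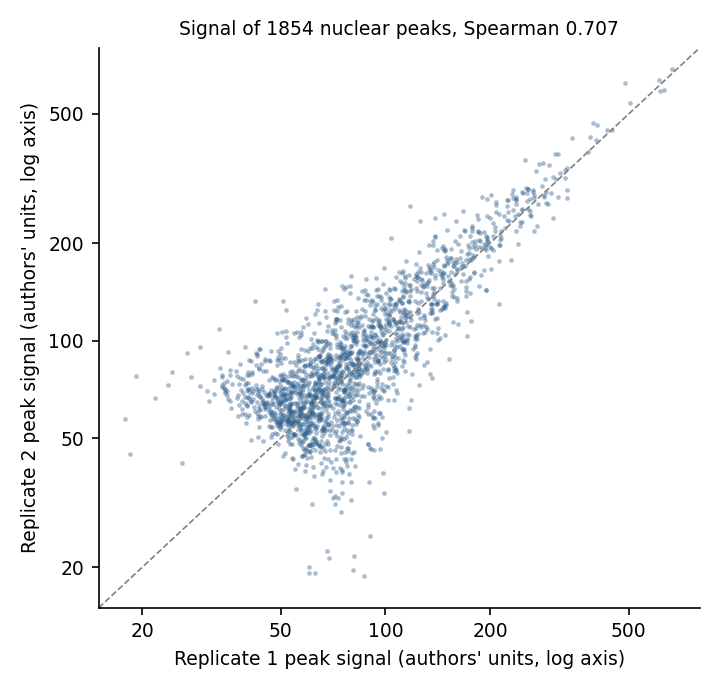
Signal of each of 1854 nuclear thresholded peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the authors' units, 1 point per peak, with the dashed line marking equal signal. Strong peaks lie close to the line and weak peaks scatter more widely around it (Spearman correlation 0.707).

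Of the 20 peaks named here by their nearest gene, 11 lay within 100 bp of a tRNA, snoRNA or snRNA gene, and 8 lay within the window that defines a bound gene for the gene named. The strongest peak (V:12303429-12303827, signal 1351.1) lay in an intron 1101 bp from the nearest transcript start, that of F55C5.17. Next came a peak 630 bp upstream of the chemoreceptor gene sre-23 (I:8259384-8259741, signal 1246.3), one near W03C9.1 (II:11960655-11961028, signal 1221.4) and one 527 bp upstream of K12H4.5 (III:8043805-8044148, signal 1204.4). The next nearest genes in order of signal were cutl-18, hrg-5, str-56, pxn-1, C04A11.5 and T02E1.2. The strongest peak in front of a ribosomal protein gene lay 285 bp upstream of rpl-3, for a protein of the large ribosomal subunit (III:3867438-3867720, signal 815.21). The remaining genes among the 20 were Y37A1B.7, his-68, Y43F8C.7, F39B2.3, Y44E3A.1, col-181, atx-2, M01F1.9 and twk-5. The histone gene his-68 had its peak 177 bp upstream of the start (signal 762.77), and atx-2, the ataxin-2 homologue, had its peak 66 bp upstream (signal 667.06). All 20 peaks ranked 28th or better among the nuclear regions of each replicate list.

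CND-1 peaks were concentrated in promoters and avoided coding exons. Promoters held 710 summits, or 36.6% (95% exact interval 34.5 to 38.8), against 13.8% after random shifts, a ratio of 2.66. The strongest regions of the replicates gave 35.7% ± 0.35 (SD, n = 2). Non-coding genes held 8.45% of summits against 3.56% after shifts. Coding exons held 2.06% (3.66% and 4.59% in replicates 1 and 2 alone) against 21.6%, 3′ UTRs 0.670% against 2.84%, and introns 23.5% against 31.0%. Each of these 5 shares differed from the shifts with a permutation p of 0.0002, the smallest the shifts can give, which is 0.00028 after adjustment over the 7 categories. The shares in intergenic sequence (27.7% against 26.5%, adjusted permutation p = 0.26) and 5′ UTRs (1.03% against 0.700%, adjusted permutation p = 0.15) did not pass the test. The median summit lay 814 bp from the nearest transcript start of a protein-coding gene, and 16.5% of summits lay beyond 3000 bp.

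**Figure D2:**
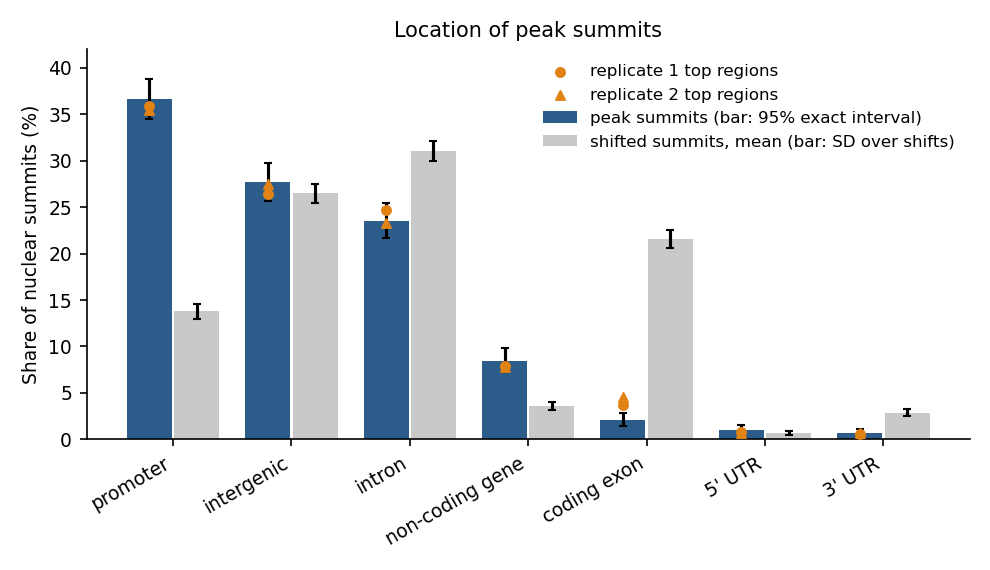
Share of the 1940 nuclear summits in each annotation category (blue, with 95% exact intervals), in the strongest regions of replicate 1 (circles) and replicate 2 (triangles), and after 10000 random shifts (grey, mean with SD over shifts). Promoters hold 36.6% of summits against 13.8% after shifts, and coding exons 2.06% (3.66% and 4.59% in the replicates) against 21.6%.

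Chromosome X carried more peaks for its length than the autosomes. It held 475 of the 1940 peaks (24.5%, 95% exact interval 22.6 to 26.5), against 17.7% of nuclear sequence and 13.7% of protein-coding genes. This was 26.8 peaks per Mb on X and 17.7 per Mb on the autosomes, a ratio of 1.51 (exact binomial p = 5.16e-14). The replicates alone gave ratios of 1.43 and 1.53. Among the autosomes the density ran from 11.4 per Mb on V to 23.1 per Mb on I.

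The cnd-1 locus itself had no peak, while hlh-2 had one. The gene cnd-1 (WBGene00000561, III:5240591-5244639, minus strand) had no summit within 1500 bp of its body in any of the 4 lists, including the 3 lists of 30000 regions. The nearest thresholded summits lay 29.2 kb and 50.4 kb away from the gene. In the pooled list the nearest summits lay 29.2 kb and 26.5 kb away. No summit of any list lay in the 48.7 kb stretch that holds the gene, so the missing peak does not show that CND-1 was not bound there. The gene hlh-2, which encodes the E protein partner of bHLH factors, had a peak 1135 bp upstream of its start in intergenic sequence (I:7194857-7195252, signal 174.53, rank 727). That peak ranked 741 in replicate 1 and 738 in replicate 2, and its 100 bp summit window contained no E-box.

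**Figure D3:**
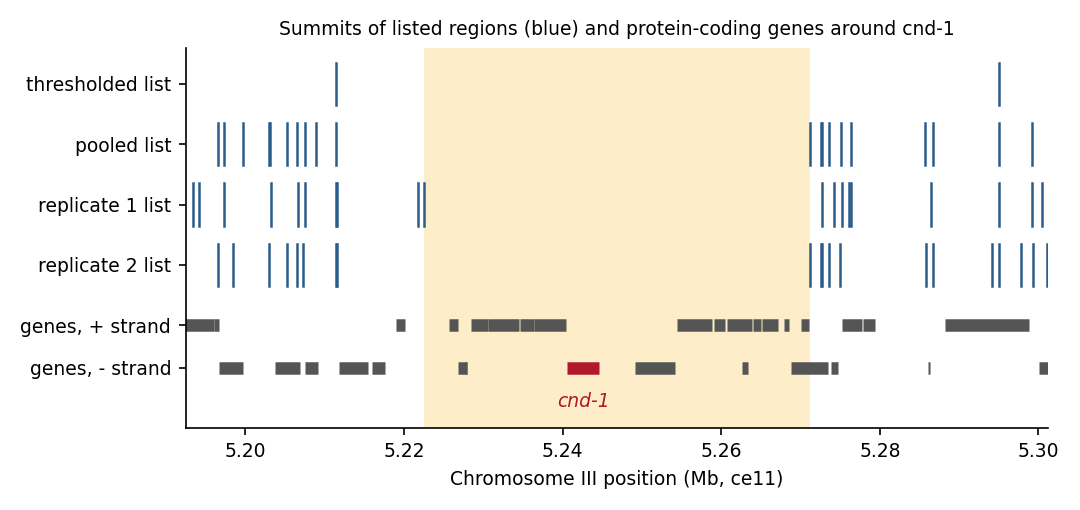
Summits of listed regions (blue lines) in the thresholded, pooled, replicate 1 and replicate 2 lists, and protein-coding genes on each strand (bars), along chromosome III in Mb of ce11, with cnd-1 in red. The shaded stretch of 48.7 kb from 5222472 to 5271184 holds 17 whole genes and no summit of any list.

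In all, 1474 protein-coding genes (7.38% of 19973) were bound, against 814 after random shifts (permutation p = 0.0002, the smallest the shifts can give). The replicates gave 1434 and 1435 bound genes. Of 24 gene lists, 5 had a higher share of bound genes than other genes, 2 had a lower share, and 17 did not pass the test. Bound means here that a summit lay in the gene's window. Whether high accessibility or transcription of promoters contributes to such summits was not tested, and the control was not used.

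Genes of the Wnt pathway and of axon guidance, ribosomal protein genes, histone genes and cell cycle regulators were bound more often than other genes. In the Wnt pathway 13 of 28 genes were bound, 6.34 times the share of other genes (Fisher's exact test, adjusted exact p = 1.44e-07). The strongest peaks there lay 192 bp upstream of mig-5 (signal 525.54) and 1092 bp upstream of dsh-1 (signal 221.65), which both encode Dishevelled proteins, 777 bp upstream of mom-1 (signal 437.78), the Porcupine homologue, at a site within 100 bp of a tRNA, snoRNA or snRNA gene, and 1403 bp upstream of hmp-2 (signal 287.44), a beta-catenin. In axon guidance and outgrowth 16 of 47 genes were bound, a ratio of 4.65 (adjusted exact p = 5.74e-07). They were led by fmi-1, a Flamingo cadherin (signal 337.45), unc-116, a kinesin heavy chain (signal 233.11), unc-115, an actin-binding protein (signal 230.78), and mab-20, a semaphorin (signal 221.77). In these lists 12 and 11 Wnt genes and 15 and 16 axon guidance genes were bound in replicates 1 and 2 alone, and the axon guidance ratio was 7.35 with the nearest gene alone. The peaks of 4 of the 13 Wnt genes and 4 of the 16 axon guidance genes ranked below 1964 in at least 1 replicate. The summits assigned to hmp-2 and to some other Wnt genes lay beyond 500 bp of those genes' starts, in promoters of other genes. Those of fmi-1 and of the Wnt gene lit-1 were assigned through transcript starts inside these genes. Since genes with several starts have more windows, the part of start number in the Wnt and axon guidance ratios is unknown.

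Among ribosomal protein genes 31 of 80 were bound, a ratio of 5.34 (adjusted exact p = 2.96e-14). After rpl-3, the strongest peaks lay 342 bp upstream of rpl-15 (signal 499.92), 288 bp upstream of rpl-20 (signal 464.07) and 452 bp upstream of rps-28 (signal 367.83). Replicates 1 and 2 alone gave 34 and 30 bound ribosomal protein genes. The ratio was 8.54 with the narrower window of 500 bp upstream and 250 bp downstream, and 4.76 against lists matched on upstream distance. Among histone genes 23 of 72 were bound, a ratio of 4.38 (adjusted exact p = 7.17e-09), led by the divergent pairs his-67 and his-68 (signal 762.77) and his-31 and his-32 (signal 462.48). With the nearest gene alone the ratio fell to 2.38 (adjusted exact p = 0.0146). Paired histone genes shared peaks, so the 23 genes rest on 14 peaks, and their values are uncertain, since histone genes have near-identical copies and reads shared between them were not tested for here. Of 29 cell cycle regulators 7 were bound, a ratio of 3.28 (adjusted exact p = 0.0173). The strongest peaks lay upstream of cdk-4 (signal 285.67), of lin-35, the retinoblastoma homologue (signal 273.05), of the kinase inhibitor gene cki-2 (signal 202.58) and of the phosphatase gene cdc-14 (signal 148.02). The cell cycle call was lost among the strongest 982 peaks (adjusted exact p = 0.266) and with a window of 500 bp upstream and 250 bp downstream (adjusted exact p = 0.124).

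Chemoreceptor and nuclear hormone receptor genes were bound less often than other genes. Only 18 of 1364 chemoreceptor genes were bound, 0.169 times the share of other genes (Fisher's exact test, adjusted exact p = 8.2e-25), a ratio of 0.267 in the strongest 982 peaks and 0.110 with the narrower window. The strongest of these peaks lay near sre-23 (signal 1246.3), srd-43 (signal 520.76), srt-11 (signal 480.3) and srt-63 (signal 405.64). Of the 18 genes 6 owed their strongest peak to a site within 100 bp of a tRNA, snoRNA or snRNA gene. Whether each listed gene, such as the bound srrt-1, encodes a chemoreceptor was not checked. How the list is spread over the chromosomes, of which V had the lowest peak density (11.4 per Mb), was not examined or corrected for. Of 269 nuclear hormone receptor genes 9 were bound, a ratio of 0.450 (adjusted exact p = 0.0315), including nhr-255, nhr-47, nhr-41 and nhr-48. The peaks of nhr-255 and nhr-41 lay within 100 bp of a tRNA, snoRNA or snRNA gene. The ratio of the nuclear hormone receptor list was 0.282 in the strongest 982 peaks. The nuclear hormone receptor call was lost with the narrower window (adjusted exact p = 0.0611) and with the nearest gene alone (adjusted exact p = 0.0657).

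Apart from axon guidance, the lists of neuronal identity and function and of glia did not pass the test with the main settings. Of 30 motor neuron fate regulators 3 were bound (adjusted exact p = 0.64), namely unc-37, the Groucho homologue (signal 373.53), ztf-11 (signal 244.37) and unc-30, the GABA neuron homeobox gene (signal 164.52). The list's ratio rose from 1.36 to 2.84 with the nearest gene alone (adjusted exact p = 0.0445). Unbound members included unc-3, unc-4 and vab-7. Of 36 pan-neuronal effectors 3 were bound (adjusted exact p = 0.85), namely syd-2, nsf-1 and the syntaxin gene unc-64, and rab-3, ric-4 and snb-1 were not. This list depended on the peaks used, with 4 and 5 bound genes in replicates 1 and 2 alone (ratios 1.55 and 1.94) and a ratio of 2.14 in the strongest 982 peaks, none past the test (smallest adjusted exact p = 0.334). None of 19 genes of neurotransmitter synthesis and transport was bound (95% exact interval 0 to 17.6%, adjusted exact p = 0.56), unc-25, unc-47 and unc-46 among them. Of 37 cilium and sensory neuron genes, daf-19, for the RFX transcription factor, was the 1 bound member (adjusted exact p = 0.66), and che-2, che-3 and che-11 were not bound. Of the 22 members of the glia list 4 were bound (egl-44, lit-1, egl-46 and dyf-7, adjusted exact p = 0.15). Whether these members are expressed in glia rather than neurons was not checked. This list passed with the nearest gene alone (ratio 3.88, adjusted exact p = 0.0136). Its unbound members included ptr-10, lin-26 and mls-2. The peak at egl-46 had no summit within 100 bp in the full list of replicate 1. Among neuropeptide genes nlp-76 and flp-23 were bound, 2 of 102 (adjusted exact p = 0.0746), both with peaks within 100 bp of a tRNA, snoRNA or snRNA gene. The neuropeptide list passed with a window of 3000 bp upstream and 1000 bp downstream (ratio 0.285, adjusted exact p = 0.0258).

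The other transcription factor lists and the Notch pathway did not pass the test. Of 41 bHLH genes hlh-2 alone was bound (adjusted exact p = 0.56), and hlh-1, hlh-3 and hlh-4 were not. Of 99 homeobox genes 7 were bound (adjusted exact p = 1). They were ceh-20, the Pbx homologue (signal 469.02), ceh-38 (signal 168.26), unc-30, ceh-86 (signal 161.86), unc-62, the Meis homologue (signal 142.62), ceh-40 (signal 133.93) and ceh-39 (signal 112.83). Replicates 1 and 2 alone gave 11 and 7 bound homeobox genes. Of 33 T-box and GATA factors egl-18 and egl-27 were bound (adjusted exact p = 1), and mab-9, mls-1 and end-1 were not. In the Notch pathway sup-17, an ADAM metalloprotease, was the 1 bound gene of 22 (adjusted exact p = 1), and lag-2, apx-1 and arg-1 were not bound.

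Genes of other tissues also did not pass the test. Of 32 body wall muscle genes 6 were bound, including unc-112, act-4, unc-60 and unc-97, but not myo-3, unc-54 or unc-15 (ratio 2.55, adjusted exact p = 0.0662). The muscle list passed with the nearest gene alone (adjusted exact p = 0.0181) and without peaks near tRNA, snoRNA and snRNA genes (adjusted exact p = 0.0386), but replicate 1 alone gave 3 bound genes (ratio 1.31, adjusted exact p = 0.592) and the strongest 982 peaks a ratio of 1.60 (adjusted exact p = 0.638). Of 31 epidermal genes 4 were bound (egl-18, let-413, ajm-1 and nhr-23, adjusted exact p = 0.49), and elt-1, elt-3 and lin-26 were not. The peak at let-413 had no summit within 100 bp in the full list of replicate 1. None of 29 intestinal genes (95% exact interval 0 to 11.9%, adjusted exact p = 0.49) and none of 21 pharyngeal genes (95% exact interval 0 to 16.1%, adjusted exact p = 0.56) was bound, among them elt-2, elt-4, elt-7, pha-4, tbx-2 and ceh-22. Of 30 germline genes spe-9 was bound (adjusted exact p = 0.85), and pgl-1, pgl-3 and glh-1 were not. The peaks of spe-9 and of the epidermal gene ajm-1 lay within 100 bp of a tRNA, snoRNA or snRNA gene. Of 156 cuticle collagen genes 4 were bound, namely col-185, col-85, col-71 and col-38 (ratio 0.346, adjusted exact p = 0.052), and col-10, col-101 and col-102 were not. Of 55 heat shock and proteasome genes 9 were bound, led by hsp-1, pbs-5, hsp-60 and pbs-4 (ratio 2.22, adjusted exact p = 0.052). Collagens passed without peaks near tRNA, snoRNA and snRNA genes (adjusted exact p = 0.00947), which took away 2 of the 4 bound collagen genes. Heat shock and proteasome genes passed in 4 settings, including replicate 2 alone (ratio 3.05, adjusted exact p = 0.0015), while the nearest gene alone gave a ratio of 1.03 (adjusted exact p = 0.908).

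**Figure D4:**
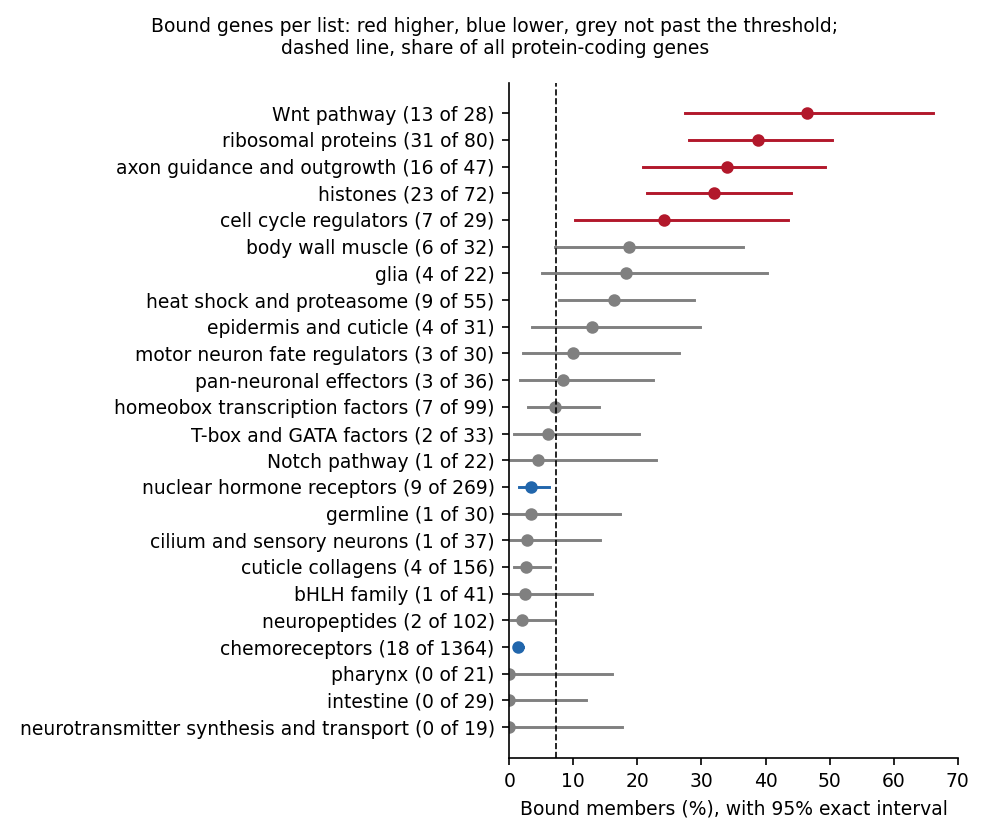
Share of bound members in each of the 24 gene lists (points) with 95% exact intervals (lines), in percent, with the bound and total members beside each name. Lists in red (5) were bound more often and lists in blue (2) less often than other genes, and the dashed line marks the 7.38% of all protein-coding genes.

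E-boxes, and above all CAGATG, were concentrated at summits. Any E-box was present in the 100 bp summit window of 958 of the 1940 peaks (49.4%, 95% exact interval 47.1 to 51.6) and in 584 flank windows (30.1%), a ratio of 1.64 (exact McNemar p = 3.52e-35). The replicates gave 48.8% ± 1.1 at summits and 32.1% ± 0.50 in flanks (SD, n = 2). CAGATG occurred in 17.4% of summit windows and 3.71% of flanks, a ratio of 4.69 (adjusted exact p = 2.31e-44) that was 2.85 in windows of 200 bp and 7.26 in the strongest 982 peaks. CAGCTG followed with 6.86% and 1.80%, a ratio of 3.8 (adjusted exact p = 1.03e-14), and CACCTG with 5.31% and 2.58%, a ratio of 2.06 (adjusted exact p = 5.62e-05). CATATG (ratio 1.87), CACATG (ratio 1.65), CAAGTG (ratio 1.62) and CAACTG (ratio 1.44) also passed the test, which made 7 of the 10 E-boxes. The last 4 lost their calls under some settings, and 4 E-boxes passed against a flank centred 1000 bp to the left. CACGTG (ratio 1.39, adjusted exact p = 0.27), CAAATG (ratio 1.01, adjusted exact p = 1) and CAATTG (ratio 0.964, adjusted exact p = 0.96) did not pass. None of these ratios was corrected for the higher G and C content of summits. The median ratio of all 6-mers with 3 G or C bases was 1.23. Base composition was tested for CAGATG only, so its part in the ratios of any E-box and of the other E-boxes is unknown.

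**Figure D5:**
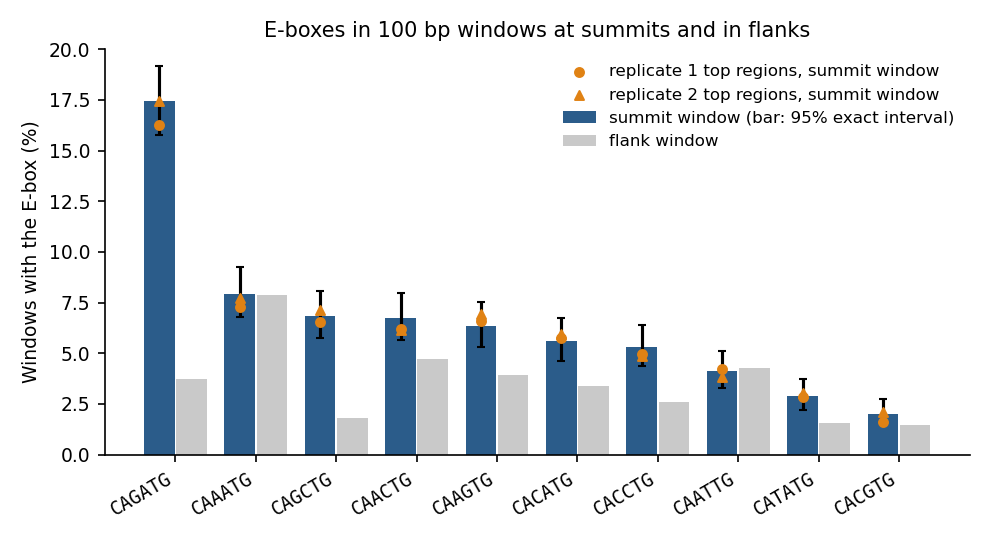
Share of 100 bp windows that contain each E-box, at summits (blue, with 95% exact intervals), in flanks (grey), and at the summits of the strongest regions of replicate 1 (circles) and replicate 2 (triangles), in percent. CAGATG stands out with 17.4% at summits and 3.71% in flanks.

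Summit sequence was also rich in G and C. The summit windows were 49.8% G and C and the flanks 35.8%. Of all 6-mers, 752 were enriched at summits, 554 of them with 4 or more G or C bases, and 452 were depleted. The largest ratios belonged to GCGCGC (15.6), CCCGGC (11.3), CGCGCG (10.5), ACGCGG (9.92), CGCACG (7.8), GCACGC (7.42), ACGCGC (7.38), ACGGCC (7.2), GCGCAC (7.0) and CGCGCA (6.5). CAGATG ranked 39th by ratio and 2nd by p-value.

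Strong peaks contained E-boxes more often than weak peaks. An E-box was present at 55.7% of the strongest 485 summits and at 42.3% of the weakest 485 (Fisher's exact test, p = 3.85e-05, adjusted exact p = 7.7e-05 over 4 features). CAGATG was present at 25.16% and 12.0% (adjusted exact p = 6.17e-07), and CAGCTG at 10.1% and 3.92% (adjusted exact p = 0.00029). Promoters held 35.1% and 32.4% of these summits, a difference of 2.68 percentage points that did not pass the test (adjusted exact p = 0.415). Its call and direction depended on the peaks used: it was 12.2 points without peaks near tRNA, snoRNA and snRNA genes (Fisher's exact test, p = 0.00035) and -7.37 points within the strongest 982 peaks (Fisher's exact test, p = 0.103). The E-box difference was 20.2 percentage points without peaks near tRNA, snoRNA and snRNA genes, but it was 2.32 percentage points and did not pass within the strongest 982 peaks (Fisher's exact test, p = 0.645).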

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

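The test of extra copies of the cnd-1 locus was chosen after the result was seen, and the other tests in this part were set before their results. The mitochondrial genome, which the comparisons above leave out, held 24 peaks of the thresholded list. Their median signal was 1150, against 150 for nuclear peaks, and 14 of the 20 strongest peaks of the whole list were mitochondrial. They covered 69.97% of the 13794 bp mitochondrial genome, and the replicate lists held 22 and 26 such regions.

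The cnd-1 gene lies in a stretch of 48.7 kb on chromosome III (5222472 to 5271184) without a single summit in the 3 lists of 30000 regions. Repeated reference sequence is argued against as the cause, since 0.0308% of the 31-mers there occurred more than once in the genome, the 1st percentile of 1000 random stretches (median 5.72%). Chance spacing was not decided by its test. Region-free stretches at least as long held 1.58% of protein-coding genes, between the bounds of 1% and 5% that had been set. That share counts the cnd-1 stretch itself and does not give what random spacing would yield. The median of all 89934 stretches was 0.206 kb. Of the 29 stretches at least as long (median repeated share 15.3%), the cnd-1 stretch was the 1 with so low a share of repeated 31-mers. Extra copies of the locus in the transgenic strain, which would raise the control as well as the immunoprecipitate, are a candidate explanation that cannot be told apart from other filtering, since peak lists hold no read depth. No biological explanation was tested.

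Summits lay within 100 bp of tRNA genes for 202 of the 1940 peaks (10.4%), against 0.186% after random shifts (permutation p = 0.0002, the smallest the shifts can give). CAGATG or CAGCTG was present at 5.45% of tRNA summits and 25.37% of other summits, a ratio of 0.215 (Fisher's exact test, p = 1.13e-12). This argues against recognition of these 2 E-boxes as the cause at most tRNA summits. The other E-boxes were not compared there. If reads were shared between identical tRNA genes, more summits had been predicted at tRNA genes with a repeated sequence. Of the 469 such genes 38.8% had a summit, against 20.98% of the 143 with a sequence found once. The ratio was 1.85 (Fisher's exact test, p = 8.19e-05), as predicted. It cannot decide whether shared reads contribute, since it is unknown how reads of repeated sequence were placed or dropped. Shared reads would also leave the 30 tRNA genes of unique sequence with a summit unexplained. High accessibility or transcription at tRNA genes was not tested.

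CAGATG was the most strongly enriched E-box at summits. Base composition of summits is argued against as the whole cause, since the ratio of CAGATG (4.69) ranked 1st among the 640 6-mers with 3 G or C bases. It lay at percentile 99.8, where the median ratio was 1.23. The next in rank were GACAGA (3.95), GCCTTA (3.93), AGAGAG (3.89) and TACGCA (3.70). None of these is an E-box, so ratios not far below that of CAGATG were also reached by other sequences. Recognition of this E-box by CND-1 or a partner is in line with a ratio of 8.10 at the 992 summits outside promoters and away from tRNA, snoRNA and snRNA genes (exact McNemar p = 1.1e-46). It remains a hypothesis, and whether CND-1 or another bHLH protein at the same sites accounts for the sequence was not tested.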

How the results depend on the processing

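Removing peaks near tRNA, snoRNA and snRNA genes was chosen after seeing the data, and the other alternatives were set before. The promoter share, the share of any E-box and the density on X kept their direction and their side of the threshold under each alternative run for them. So did the number of bound genes, except with nearest genes (1408), where it was not tested. Where a value moved or turned, the cause was not tested. The strongest 982 peaks bound 781 genes, lost the E-box difference between strong and weak peaks (2.32 points) and turned the promoter difference to -7.37 points. That promoter difference, not past the threshold before, was -1.44 and -0.825 points with the wider and narrower promoter, -0.547 to 0.0720 points without 1 replicate, and 12.2 points and past the threshold without peaks near small RNA genes, where 11 gene lists passed, the neuropeptide list with 0 bound genes by construction. The share of peaks in both replicates was 56.6% within 50 bp, 70.6% within 200 bp, 71.1% with 1 bp of overlap, 62.2% with mutual overlap and 89.6% against replicate lists of doubled length. The correlation was 0.751 within 50 bp. The narrower gene window bound 873 genes, and 4 E-boxes passed against the flank 1000 bp to the left. Ratios that turned belonged to lists and E-boxes not past the threshold in either setting. Homeobox genes had 1.03 in the strongest 982 peaks, 1.06 without peaks near small RNA genes, 1.16 with the narrower window, 1.87 with nearest genes, 1.01 with matched lists, and 0.984 to 1.55 without 1 replicate. Notch genes had 1.16 in the strongest 982 peaks, 1.04 with the narrower window, 1.94 with nearest genes, and 1.27 without either replicate. T-box and GATA factors had 1.55 in the strongest 982 peaks and 1.29 with nearest genes. Epidermal genes had 0.825 in the strongest 982 peaks and 0 with the narrower window. CAAATG had 1 with merged peaks, 0.810 and 0.953 in windows of 50 and 200 bp, 0.963 and 0.994 against the right and the far flank, and 0.792 to 1.03 without 1 replicate. CAATTG had 1.03 in the strongest 982 peaks, 1.12 without peaks near small RNA genes, and 1.11 and 1 against those flanks. CACGTG had 0.969 to 1.21 without 1 replicate. Of the other values for single lists, E-boxes and genes, 410 kept their direction and call or stayed within rank 1964, 15 lost and 11 gained a call, and of the peaks of named genes 4 (ajm-1, dyf-7, nhr-23 and unc-97) ranked below 1964 in 1 replicate. Of all 160 bound list members 30 ranked below 1964 or had no rank in at least 1 replicate. The peaks at let-413 and egl-46 gave no rank in replicate 1, whose full list had no summit within 100 bp of them. Depth cannot be read from peak lists, so it is unknown how many weak sites the threshold leaves out.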

Other observations

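The comparisons in this part were chosen after the data were seen. Strong peaks were more frequent than weak ones at tRNA and snoRNA genes and at genes annotated as ncRNA. Of the 612 tRNA genes, 212 had a summit within 100 bp, and such summits made up 21.9% of the strongest 485 peaks and 3.71% of the weakest 485 (Fisher's exact test, p = 2.45e-18). Summits within 100 bp of snoRNA genes numbered 65 (3.35%, against 0.119% after random shifts) and made up 10.3% of the strongest and 1.03% of the weakest peaks (Fisher's exact test, p = 7.21e-11). Genes annotated as ncRNA had 411 summits (21.2%, against 2.44% after shifts), with 30.3% among the strongest and 15.5% among the weakest peaks (Fisher's exact test, p = 4.68e-08). Summits near snRNA genes numbered 22 (1.13%, against 0.0351% after shifts), with 1.65% among the strongest and 1.24% among the weakest peaks, a difference that did not pass the test (Fisher's exact test, p = 0.789). Near miRNA genes there were 7 summits, against 1.51 after shifts (adjusted permutation p = 0.0033). They made up 0.412% of the strongest and 0.206% of the weakest peaks, a difference that did not pass Fisher's exact test. Summits within 100 bp of protein-coding genes (847, against 1278.6 after shifts), pseudogenes (13, against 61.97) and piRNA genes (8, against 34.3) were fewer than after shifts, each with an adjusted permutation p of 0.00031.

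CAGATG was found less often at promoter summits than elsewhere. Leaving out summits near tRNA, snoRNA and snRNA genes, it was present at 81 of 659 promoter summits (12.3%) and at 243 of 992 other summits (24.5%, Fisher's exact test, p = 4.52e-10). The strongest regions of replicate 1 gave 12.4% and 22.3%, and those of replicate 2 gave 12.5% and 24.0%. In the 5 gene lists bound more often than other genes, the share of peaks with CAGATG varied. It was 5 of 17 for axon guidance genes (29.4%), 2 of 14 for histone genes (14.3%) and 2 of 15 for Wnt genes (13.3%). For ribosomal protein genes it was 1 of 30 (3.33%) and for cell cycle regulators 0 of 8. Among all nuclear peaks, 17.4% of summit windows and 3.71% of flanks contained CAGATG. With lists pooled, CAGATG was present at 7 of 31 peaks of axon guidance or Wnt genes. At ribosomal protein or histone genes it was present at 3 of 44 peaks. This difference did not pass Fisher's exact test (p = 0.0816).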
